A study of Mus musculus with 11 samples.

How the data were processed

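Gene expression in sorted NK cells from mouse spleen was measured on 11 Agilent one-colour arrays, 1 per sample. Per the labels' protocols, spleen cells of female C57Bl/6 mice were stained for CD3ε, CD19, NK1.1, CD11b, CD27 and CD117 and sorted on a MoFlo instrument, and the RNA was labelled with Cy3 by a low-input method. The scanner files hold, per the file headers, a processed signal intensity for each spot, on a linear scale, after background subtraction and detrending by Agilent Feature Extraction; it was not normalized between arrays. The submitters' processing notes name version 9.5.1 of that software and the file headers version 10.7.3.1. The authors also deposited a table of log2 values; set against the scanner files, it is the log2 of the processed signal shifted by 1 constant per array.

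The analysis started from the scanner files. Each array held 43379 spots without controls. The log2 of the processed signal minus the array's 75th percentile was taken, spots that the software marked as non-uniform or as population outliers were left out, and spots of the same probe were averaged. Of 41174 probes 26933 matched a gene symbol through RefSeq transcript names of the GRCm38.p6 gene table and 14241 did not; only names, no coordinates, were used. A probe was kept if it was well above background on every array of at least 1 group, and the kept probe with the highest mean stood for its gene. Of 18353 genes with a probe 14068 were tested, with 79 values missing and 0 saturated spots. Other probes of the genes that changed went the other way in 28 of 300 cases for CD117+ against CD27SP cells, 38 of 761 for DP against CD27SP, 5 of 153 for CD11bSP against DP and 70 of 1216 for CD11bSP against CD27SP.

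Groups followed the sort gates in the labels. All 4 groups were fitted together with limma 3.58.1 in R 4.3.3, with group means, moderated t tests and Benjamini-Hochberg adjustment within each comparison, and genes with an adjusted p under 0.05 were said to have changed. The residual degrees of freedom were 7 and the prior degrees of freedom 2.77. The comparisons were CD117+ minus CD27SP, DP minus CD27SP, CD11bSP minus DP and CD11bSP minus CD27SP, and 2 further pairs were counted only. Where a gene was well above background on no array of the dimmer group, its change is given as "at least N-fold", a bound from the background level of that group. A gene dim on only some arrays of that group has a plain change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

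Gene lists of cell type markers, NK cell functions and general processes, 32 in all, were fixed before the files were read. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the 32 lists. Counts "adjusted over the list alone" use adjusted p-values computed inside that list. Genes to be named were chosen by a rule written before the files were read. They are the 8 largest rises and 8 largest falls per comparison among genes with an adjusted p under 0.05, a log2 change of 1 or more, groups that do not overlap and signal well above background on all arrays of the brighter group. To these come up to 4 members per list with the largest change that passed, and the genes of the sort molecules.

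Arrays were scanned on 3 slides, read from the file headers. The CD27SP arrays and DP array 3 lay on slide 3, which was scanned on another day. Slide was not part of the fit; alternatives with the slide as a block, and differences within a slide where both groups lay on it, stand beside the results. Equal replicate numbers were checked by the correlation of the deviations of same-numbered arrays from their group means. It was 0.61, 0.40 and 0.28 for CD27SP and DP cells and 0.57, 0.51 and 0.37 for CD27SP and CD11bSP cells, which met the rule set for a pairing from the data, over 0.1 in all 3 pairs. It was 0.67, 0.47 and 0.0089 for DP and CD11bSP cells, which did not, and CD117+ cells had 2 pairs only. The labels do not say what the numbers stand for. The rule was applied to each pair of groups on its own. The fit with group means alone used no pairing.

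The alternatives were quantile scaling, scaling to the array median, normexp background correction of the raw median signal (the mean signal planned for it is not in the files), the authors' table, other filters and probe choices, spots kept whatever their marks, blocks for replicate number, slide and scan day, fits of the 2 groups alone, array weights, other thresholds and each array left out. The pipeline was tested on simulated data with 14068 genes and 200 changed genes. At log2 changes of 1, 2 and 3 it recovered 28 of 67, 58 of 67 and 59 of 66 genes for CD117+ against CD27SP cells, with 10 unchanged genes passing. For DP against CD27SP it recovered 27, 62 and 62 with 8 unchanged genes passing, for CD11bSP against DP 34, 60 and 61 with 11, and for CD11bSP against CD27SP 25, 54 and 63 with 6. In each comparison all 3 shifted lists passed and 0 of 23 untouched lists did. The simulated noise was independent for each gene and array, without slide or replicate effects. The simulation therefore does not show how the gene and list tests behave where genes or arrays are correlated.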

Results

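Gene expression was measured in natural killer (NK) cells, lymphocytes that kill infected or transformed cells, sorted from the spleen of female C57Bl/6 mice. Cells stained for NK1.1 were parted by 3 surface molecules, namely CD117 (the receptor of stem cell factor), CD27 (a member of the TNF receptor family) and CD11b (an integrin chain). The groups were CD117+CD27+CD11b− cells (called CD117+ here, 2 arrays), CD117−CD27+CD11b− cells (CD27SP, 3 arrays), CD117−CD27+CD11b+ cells (DP, 3 arrays) and CD117−CD27−CD11b+ cells (CD11bSP, 3 arrays). The 11 arrays lay on 3 slides. The 75th percentile of the spot signal ran from 280.9 on DP array 2 to 1600 on CD11bSP array 1. Spots well above background made up 64.0% to 77.2% of an array, except on CD117+ array 2, where they made up 84.3%. Nothing in the labels says that arrays of one group came from separate animals, so the p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision. Values are log2 signals relative to the array's 75th percentile, differences carry their standard error (SE), and adjusted p-values are from limma.

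The genes of 2 of the surface molecules used in the sort were measured. Cd27 had a mean of 2.67 ± 0.05 (SD, n = 3) in CD27SP cells, 2.09 ± 0.28 (n = 2) in CD117+ cells, 1.92 ± 0.22 (n = 3) in DP cells and -0.33 ± 0.09 (n = 3) in CD11bSP cells. Itgam, which encodes CD11b, had a mean of -0.15 ± 0.56 in CD27SP cells, -0.52 ± 0.71 in CD117+ cells, 3.099 ± 0.21 in DP cells and 3.84 ± 0.11 in CD11bSP cells. From CD27SP to DP cells Itgam rose by 3.25 (SE 0.31, adjusted p = 0.000144) and Cd27 fell by 0.75 (SE 0.16, adjusted p = 0.0107; -0.50, adjusted p = 0.148, with the slide as a block), and from DP to CD11bSP cells Cd27 fell by 2.24 (SE 0.16, adjusted p = 0.000203) and Itgam did not pass (0.74, SE 0.31, adjusted p = 0.338). Between CD27SP and CD11bSP cells Cd27 fell by 3.00 (SE 0.16, adjusted p = 1.73e-06) and Itgam rose by 3.99 (SE 0.31, adjusted p = 2.07e-05). Neither gene passed between CD117+ and CD27SP cells (-0.58, SE 0.18, adjusted p = 0.0892 for Cd27 and -0.37, SE 0.35, adjusted p = 0.55 for Itgam). Both follow the gates and are no finding. No probe carried the gene name of CD117 in the table of names used here, so that gate was not checked with its own gene.

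**Figure D1:**
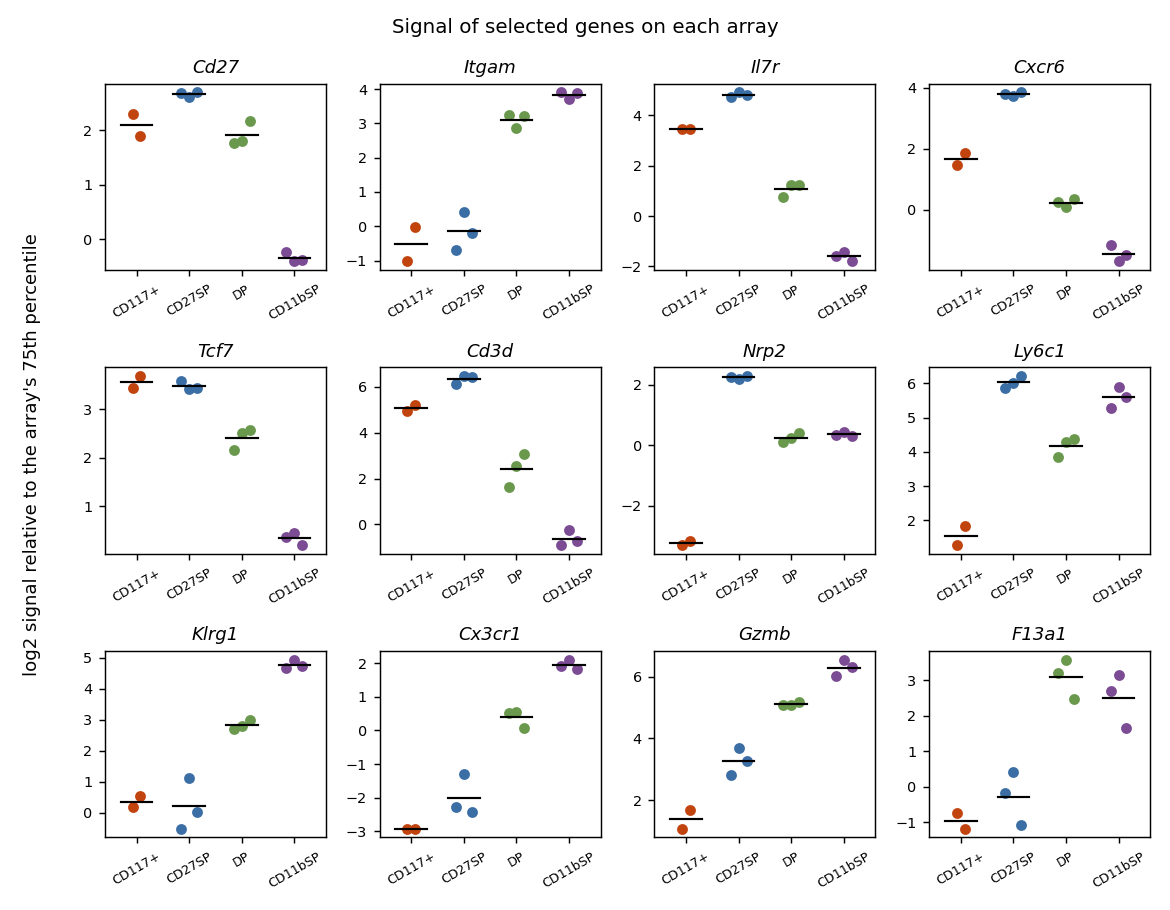
Each panel plots 1 gene, with the 4 sorted groups on the x axis and log2 signal relative to the array's 75th percentile on the y axis; points are single arrays and black lines are group means. Cd27 lies at 2.67 in CD27SP and -0.33 in CD11bSP cells, Klrg1 at 0.22 and 4.78, and Nrp2 at -3.23 in CD117+ and 2.25 in CD27SP cells.

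The first comparison set CD117+ against CD117− cells inside the CD27+CD11b− gate. Nrp2, a co-receptor for semaphorins, fell by 5.48 on the log2 scale in CD117+ cells (SE 0.15, adjusted p = 1.05e-07, n = 2 and 3), from a mean of 2.25 ± 0.06 to -3.23 ± 0.11 (SD). Gramd3 fell by 5.21 (SE 0.20, adjusted p = 1.48e-06) and Dapl1 fell by 5.16 (SE 0.52, adjusted p = 0.000516). Drc1 fell by 5.07 (SE 0.43) and Apobec2 fell by 4.84 (SE 0.66). Tdrp and Lratd1 were not well above background on either CD117+ array and were at least 21.4-fold and at least 30.3-fold lower there (adjusted p = 8.17e-05 and 0.000294). Among the genes that rose, Spp1, which encodes the secreted protein osteopontin, gained 3.19 (SE 0.23, adjusted p = 8.17e-05), and the transcription factor gene Batf3 gained 2.37 (SE 0.34, adjusted p = 0.00339). An 84.3% share of spots well above background set CD117+ array 2 apart, and most of the largest rises were in genes with little signal elsewhere. Agxt2 (measured on 1 CD117+ array after 1 spot was left out), Speer3, Nrxn3 and Esrp1 were not well above background on any CD27SP array and were at least 19.6, 18.6, 12.6 and 12.6-fold higher in CD117+ cells. Fam163a, Irs1 and Rgs7bp, in the same state, were at least 13.3, 10.8 and 10.0-fold higher, and Pnoc, the prepronociceptin gene, rose by 4.94 (SE 0.77).

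The fixed gene lists placed these changes in groups. Of 21 measured late NK stage markers, genes known to be high in mature NK cells, 6 fell and 1 rose (7 and 1 adjusted over the list alone). The median was -0.24 and the list passed at adjusted p = 0.00177, and adjusted p = 0.847 with an estimated correlation. Ly6c1 and Ly6c2, which encode surface antigens, fell by 4.49 (SE 0.25) and fell by 3.96 (SE 0.32). The potassium channel gene Kcnj8 fell by 3.16 (SE 0.385), and Gzmb, which encodes the cytotoxic protease granzyme B, fell by 1.89 (SE 0.28). Of 20 early NK stage markers 5 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.15). Gpr183, an oxysterol receptor gene, fell by 2.55 (SE 0.23), Ikzf2, the gene of Helios, by 2.08 (SE 0.16), Il18r1, an interleukin-18 receptor gene, by 1.64 (SE 0.28), and Il7r, the interleukin-7 receptor gene, by 1.36 (SE 0.19). That list passed at adjusted p = 0.00178, and adjusted p = 0.847 with an estimated correlation. Of 30 trafficking receptors 8 fell and 3 rose (11 and 3 adjusted over the list alone; median -0.45, adjusted p = 0.00152, and adjusted p = 0.642 with an estimated correlation). The sphingosine-1-phosphate receptor gene S1pr1, needed for exit from lymphoid organs, fell by 3.75 (SE 0.30), the lymph node homing receptor gene Ccr7 by 2.73 (SE 0.48) and Cxcr6 by 2.13 (SE 0.20).

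Genes better known from T cells were also lower in CD117+ cells. Of 15 measured T cell markers 7 fell and 0 rose (10 and 2 adjusted over the list alone; median -1.01, adjusted p = 1.74e-07, and adjusted p = 0.318 with an estimated correlation). Cd5 fell by 4.71 (SE 0.25), Cd6 by 4.33 (SE 0.27), Cd3e by 2.76 (SE 0.48), Cd8a by 2.48 (SE 0.33) and Bcl11b, a transcription factor gene of the T lineage, by 1.91 (SE 0.32). With the slide as a block Cd5, Cd6, Cd3e, Cd8a and Bcl11b had -4.25, -3.93, -3.66, -1.45 and -0.92 (adjusted p = 0.0105, 0.0118, 0.141, 0.294 and 0.617), and the list still passed (adjusted p = 1.15e-06). Cd8a turned direction with normexp (0.92). It turned too with only probes above background on all arrays (0.275), where another Cd8a probe stood for the gene, so probes of Cd8a differed in direction. Lef1, another such factor, fell by 2.76 (SE 0.32). Cd4, chosen after its values were seen, did not pass (0.97, SE 0.33, adjusted p = 0.117). Of 11 Ly49 receptor genes 7 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.965, adjusted p = 1.69e-05, adjusted p = 0.648 with normexp, and adjusted p = 0.318 with an estimated correlation). Klra17 rose by 2.49 (SE 0.25), Klra6 by 1.69 (SE 0.27; 0.71, adjusted p = 0.548, with the slide as a block), Klra4 by 1.49 (SE 0.25) and Klra10 by 1.40 (SE 0.20). Ly49 genes are near-identical copies, so which member a probe reads is uncertain. Of 29 other NK receptors 3 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.50, adjusted p = 0.00169, adjusted p = 0.194 without CD117+ array 1 and 0.547 with normexp, which turned its direction, and adjusted p = 0.642 with an estimated correlation). Klri2 rose by 1.37 (SE 0.22). Ncr1, which encodes the activating receptor NKp46, rose by 0.77 (SE 0.18, adjusted p = 0.0349). Among cytokines and chemokines 4 of 23 rose and 1 fell (4 and 1 adjusted over the list alone), with no shift of the list (median 0.05, adjusted p = 0.641). Csf2, the GM-CSF gene, rose by 1.51 (SE 0.25), Ccl4 by 1.43 (SE 0.32) and Ccl3 by 1.29 (SE 0.30). The costimulatory receptor gene Tnfrsf9 rose by 1.75 (SE 0.20) and the activation marker gene Cd83 by 1.59 (SE 0.29). The transcription factor genes Irf4 and Egr2 rose by 1.83 (SE 0.345) and 1.17 (SE 0.22).

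Of 67 cell cycle genes 5 rose and 0 fell (7 and 0 adjusted over the list alone; median 0.55, adjusted p = 8.39e-05, and adjusted p = 0.847 with an estimated correlation). That shift rested on CD117+ array 1: without it the list did not pass and its direction turned (adjusted p = 0.584). The list's mean was -0.121 on CD117+ array 1, -0.824 on array 2 and -0.682, -1.13 and -1.35 on the CD27SP arrays. Kif2c, a mitotic kinesin gene, rose by 2.31 (SE 0.54) and Gins2, a replication gene, by 1.06 (SE 0.25). Haematopoietic progenitor markers (3 of 23 rose, 0 fell; 7 and 0 adjusted over the list alone; median 0.495, adjusted p = 0.00305), MHC class II genes (2 of 13 rose, 0 fell; 2 and 0 adjusted over the list alone; median 0.87, adjusted p = 0.00793) and plasma cell markers (1 of 6 rose, 0 fell; 1 and 0 adjusted over the list alone; median 0.91, adjusted p = 0.0493) shifted upwards, each at adjusted p = 0.847 with an estimated correlation. The 45 ribosomal protein genes had a median of -0.25 and the 34 genes of ribosome biogenesis and MYC one of -0.29; no single member passed, over all genes or adjusted over the list alone. Both lists passed the list test (adjusted p = 0.00631 and 0.00104), and adjusted p = 0.861 and 0.847 with an estimated correlation. Without CD117+ array 1 the MHC class II, plasma cell and ribosomal protein lists did not pass either (adjusted p = 0.0909, 0.358 and 0.0667), nor plasma cell markers without CD27SP array 3, DP array 2, DP array 3 or CD11bSP array 2 (adjusted p = 0.129, 0.0529, 0.0684 and 0.0581). With normexp the MHC class II and plasma cell lists did not pass (adjusted p = 0.0871 and 0.0935). With quantile scaling the early NK stage, haematopoietic progenitor, plasma cell, ribosomal protein and ribosome biogenesis lists no longer passed (adjusted p = 0.134, 0.321, 0.134, 0.0543 and 0.122), and with the array median as the scale the other NK receptors did not (adjusted p = 0.0711). With the replicate number as a block and CD117+ array 2 put with number 3, the early NK stage and ribosomal protein lists did not pass (adjusted p = 0.0522 and 0.198). The medians with the slide as a block were -0.32 for late and -0.06 for early NK stage markers, -0.30 for trafficking receptors, -0.495 for T cell markers, 1.12 for Ly49 receptors, 0.38 for other NK receptors and 0.68 for cell cycle genes. They were 0.15 for progenitor markers (adjusted p = 0.229), 0.72 for MHC class II genes, 1.11 for plasma cell markers, -0.29 for ribosomal proteins and -0.05 for ribosome biogenesis and MYC (adjusted p = 0.102). Monocyte, neutrophil and oxidative phosphorylation genes, which did not pass in the fit with group means alone (adjusted p = 0.472, 0.297 and 0.0852), passed downwards in that fit (medians -0.314, -0.595 and -0.20, adjusted p = 0.00971, 0.00213 and 0.0453).

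In all, 546 genes were higher and 333 lower in CD117+ cells among 14068 genes tested, 879 together. Quantile scaling gave 270 higher and 500 lower, and scaling to the array median 270 higher and 1040 lower, with the median of all genes shifted to -0.54. In the fit with the slide as a block 43 genes remained (6 higher, 37 lower; all 43 among the 879), and all 879 kept their direction. The median SE went from 0.249 to 0.359, and of the 49 genes named here that changed, 14 passed in that fit. No slide held both groups, so no value within a slide could be had. The count was 477 (178 higher, 299 lower) without CD117+ array 2, 2295 without CD117+ array 1, of which 2022 were higher, and 475, 553 and 392 without CD27SP arrays 1, 2 and 3 (268, 335 and 213 higher).

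The second comparison followed the gain of CD11b on CD27+ cells, from CD27SP to DP. Il7r fell by 3.75 (SE 0.17, adjusted p = 6.26e-06, n = 3 and 3), from 4.82 ± 0.10 to 1.07 ± 0.29 (SD), and the chemokine receptor gene Cxcr6, known from tissue-resident lymphocytes, fell by 3.56 (SE 0.18, adjusted p = 6.26e-06). The largest falls were those of Lratd1 (by 5.37, SE 0.46), Tdrp (by 5.23, SE 0.41), Drc1 (by 4.82, SE 0.38), Lypd6b (by 4.38, SE 0.27) and Dapl1 (by 4.16, SE 0.47). Adh1, Atp6v0d2 and Susd4 were not well above background on any DP array and were at least 16.4, 8.21 and 4.96-fold lower there. Klrg1, an inhibitory receptor gene of mature NK cells, rose by 2.61 (SE 0.34, adjusted p = 0.000639), and the fractalkine receptor gene Cx3cr1 rose by 2.39 (SE 0.28, adjusted p = 0.00036). The largest rises included Mfsd7a (4.18, SE 0.69), Retnla (4.13, SE 0.91), the mast cell protease gene Mcpt4 (3.93, SE 0.67), Ifi205 (3.77, SE 0.93) and the myeloid receptor gene Clec5a (3.70, SE 0.60). Pstpip2, Guca1a and Tlr8 were not well above background on any CD27SP array and were at least 6.67, 4.39 and 3.65-fold higher in DP cells.

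Of 20 early NK stage markers 11 fell and 0 rose (12 and 0 adjusted over the list alone; median -1.0, adjusted p = 1.06e-07, and adjusted p = 0.238 with an estimated correlation). Ikzf2 fell by 3.00 (SE 0.14), Gpr183 by 2.40 (SE 0.21) and Tnfsf10, the gene of the death ligand TRAIL, by 1.89 (SE 0.21). Of 21 late NK stage markers 13 rose and 2 fell (15 and 3 adjusted over the list alone; median 1.25, adjusted p = 7.67e-06, and adjusted p = 0.496 with an estimated correlation). Cma1, a protease gene, rose by 2.66 (SE 0.56), Gzmb by 1.84 (SE 0.25), Gzma by 1.72 (SE 0.39) and the transcription factor gene Zeb2 by 1.63 (SE 0.28). Of 19 markers of type 1 innate lymphoid cells (ILC1), a lymphocyte kind close to NK cells, 14 fell and 0 rose (15 and 0 adjusted over the list alone; median -1.61, adjusted p = 6.36e-14, and adjusted p = 0.0647 with an estimated correlation). Of these 19 markers 15 stand in another list too. So do 16 of the 20 early NK stage and 6 of the 15 T cell markers, so falls of these lists are not wholly separate results. ILC3 markers (5 of 16 fell, 1 rose; 6 and 1 adjusted over the list alone; median -0.23) passed at adjusted p = 0.0465, and adjusted p = 0.404 with an estimated correlation. That call was lost with the replicate number as a block (adjusted p = 0.149), with the array median as the scale (adjusted p = 0.0906) and in the authors' table (adjusted p = 0.0858). It was lost too with normexp (adjusted p = 0.209) and without CD117+ array 1 or 2, CD27SP array 1 or 2, or DP array 3 (adjusted p = 0.0741, 0.0742, 0.058, 0.0542 and 0.144). Of 15 T cell markers 12 fell and 0 rose (14 and 0 adjusted over the list alone; median -2.70, adjusted p = 6.36e-14, and adjusted p = 0.072 with an estimated correlation). Cd5 fell by 4.15 (SE 0.22), Cd3d by 3.94 (SE 0.32), Cd3g by 3.32 (SE 0.23) and Bcl11b by 3.30 (SE 0.29). T cells in the CD27SP sort stay open as a source of the T cell marker falls. Id3, a transcription regulator gene, fell by 3.02 (SE 0.27), and the TNF family genes Lta and Tnfsf8 fell by 3.24 (SE 0.24) and 2.86 (SE 0.21). Of 11 Ly49 receptor genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.27, adjusted p = 2.77e-06, and adjusted p = 0.072 with an estimated correlation). Klra4 rose by 1.60 (SE 0.22). The Fc receptor gene Fcgr3, which mediates antibody-dependent killing, rose by 1.35 (SE 0.17).

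Markers of several other cell types rose with CD11b, though not of all. Of 29 monocyte and macrophage markers 28 rose and 0 fell (29 and 0 adjusted over the list alone; median 2.49, adjusted p = 1.91e-23, and adjusted p = 0.139 with an estimated correlation). F13a1, the coagulation factor XIII A chain gene, rose by 3.38 (SE 0.47), Lyz2, the lysozyme gene, by 3.03 (SE 0.43) and Mpeg1 by 3.00 (SE 0.38). Neutrophil markers (17 of 21 rose, 0 fell; 19 and 0 adjusted over the list alone; median 2.67, adjusted p = 6.36e-14, and adjusted p = 0.148 with an estimated correlation) rose too. Among them Chil3 rose (3.08, SE 0.49) and the G-CSF receptor gene Csf3r (3.08, SE 0.51). Mast cell and basophil markers (14 of 16 rose, 0 fell; 14 and 0 adjusted over the list alone; median 2.54, adjusted p = 5.78e-14, and adjusted p = 0.072 with an estimated correlation) rose too. Among them the basophil protease gene Mcpt8 rose (2.89, SE 0.49). Platelet and megakaryocyte markers (14 of 16 rose, 0 fell; 14 and 0 adjusted over the list alone; median 2.13, adjusted p = 6.71e-13, and adjusted p = 0.072 with an estimated correlation) rose too. Among them Ppbp rose (2.41, SE 0.26). Erythroid markers (10 of 16 rose, 0 fell; 12 and 0 adjusted over the list alone; median 2.19, adjusted p = 2.58e-09, and adjusted p = 0.0895 with an estimated correlation) rose too. Among them the water channel gene Aqp1 rose (2.90, SE 0.32). Haematopoietic progenitor markers (17 of 23 rose, 0 fell; 19 and 0 adjusted over the list alone; median 2.39, adjusted p = 5.37e-13, and adjusted p = 0.148 with an estimated correlation) rose too. Among them Mpo rose (3.20, SE 0.68) and Cd34 (2.85, SE 0.29). B cell markers had no such shift (2 of 16 rose and 3 fell; 2 and 3 adjusted over the list alone; median 0.17, adjusted p = 0.958). The dendritic cell (4 of 15 rose and 3 fell; 7 and 4 adjusted over the list alone), ILC2 (4 of 15 rose and 2 fell; 4 and 4 adjusted over the list alone) and plasma cell lists (0 of 6 rose and 0 fell; 2 and 0 adjusted over the list alone) did not pass either (medians 0.40, 0.20 and 0.60, adjusted p = 0.606, 0.606 and 0.362). MHC class II genes (6 of 13 rose, 0 fell; 6 and 1 adjusted over the list alone; median 1.43, adjusted p = 0.00599, and adjusted p = 0.496 with an estimated correlation) rose too. Among them H2-Aa rose (2.23, SE 0.40), H2-Ab1 (2.03, SE 0.30) and their transcriptional activator gene Ciita (1.87, SE 0.32). Of 67 cell cycle genes 24 rose and 0 fell (45 and 0 adjusted over the list alone; median 0.98, adjusted p = 1.59e-12, and adjusted p = 0.431 with an estimated correlation). Hmmr rose by 1.85 (SE 0.38) and the mitotic kinase gene Aurkb by 1.73 (SE 0.39). Of 34 genes of ribosome biogenesis and MYC 3 fell and 0 rose (3 and 0 adjusted over the list alone; median -0.31, adjusted p = 0.000143, and adjusted p = 0.49 with an estimated correlation).

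DP array 3 shared slide 3 with the CD27SP arrays. As these lay on that slide alone, the fit with the slide as a block takes its difference from DP array 3 by construction and is the difference within the slide, resting on 1 DP array. The list medians were then -0.83 for early and 1.44 for late NK stage markers, -1.65 for ILC1 and -0.15 for ILC3 markers, -2.51 for T cell markers, 1.21 for Ly49 receptors, 2.20 for monocyte and macrophage, 2.38 for neutrophil, 2.55 for mast cell and basophil and 2.17 for platelet markers. For erythroid markers the median was 2.12, for progenitor markers 2.11, for MHC class II genes 1.04, for cell cycle genes 0.87, for B cell markers -0.23 and for ribosome biogenesis and MYC -0.15. The shifts of NK identity genes (4 of 18 rose, 0 fell; 4 and 0 adjusted over the list alone; median 0.27, adjusted p = 0.061) and ribosomal proteins (0 of 45 rose and 1 fell; 0 and 0 adjusted over the list alone; median -0.14, adjusted p = 0.061) did not pass, and both passed with the replicate number as a block (adjusted p = 0.0295 and 0.0179). With the slide as a block NK identity genes (median 0.49, adjusted p = 0.00377) and the 22 cytotoxic effectors (6 rose and 2 fell; 9 and 2 adjusted over the list alone; median 0.31, adjusted p = 0.0971; 0.43 and adjusted p = 0.0123 with the block) also passed.

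From CD27SP to DP cells 1278 genes rose and 691 fell, 1969 in all. Quantile scaling gave 1049 higher and 905 lower, and scaling to the array median 904 higher and 939 lower, with the median of all genes shifted to -0.34. When the slide was a block 835 genes changed (573 higher, 262 lower), 817 of them among the 1969. Of the 51 genes named here that changed, 33 passed in that fit. Within slide 3 the 1 DP array against 3 CD27SP arrays gave 1053 genes (755 higher, 298 lower), with the lone array assumed to vary like the others. Without CD27SP array 3 the count was 1261 (876 higher, 385 lower), and without DP array 3 it was 2641 (1418 higher, 1223 lower). The genes that were lower numbered 450 and 446 without CD27SP arrays 1 and 2 and 406 without DP array 1.

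**Figure D2:**
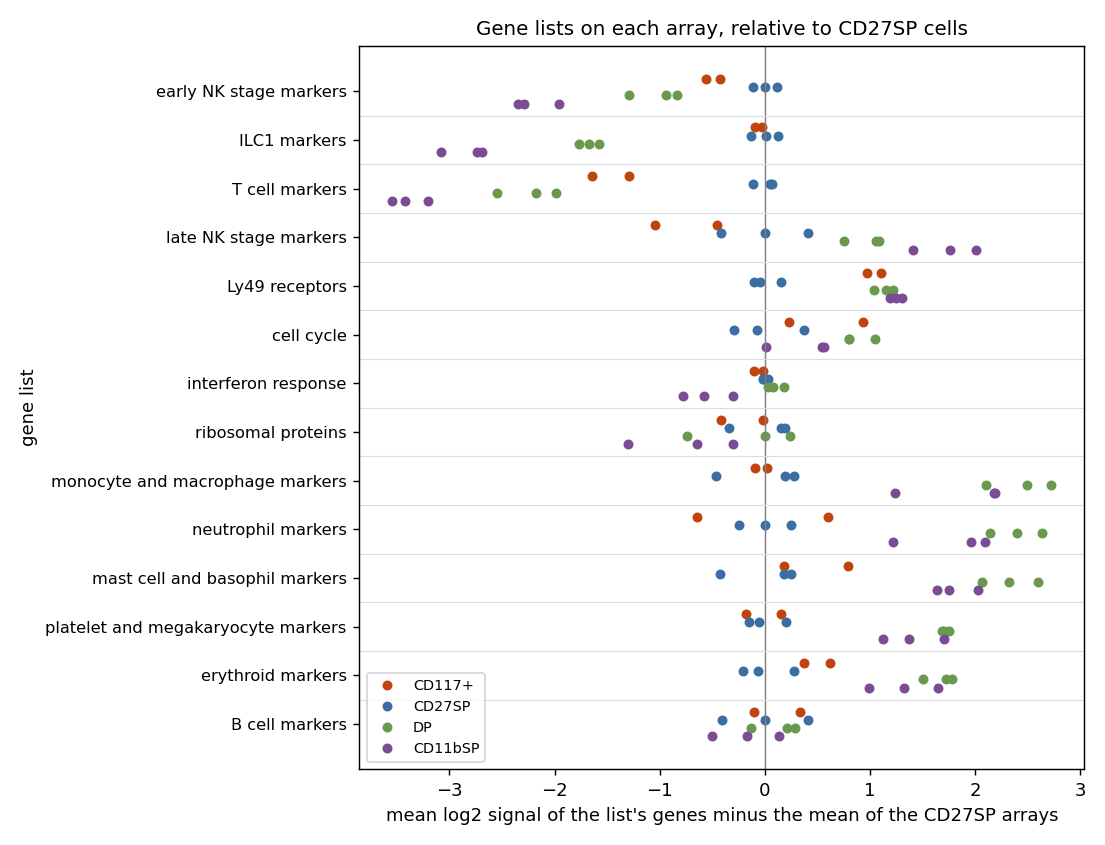
The y axis lists 14 gene lists and the x axis gives the mean log2 signal of each list's genes on an array minus the mean of the CD27SP arrays; each point is 1 array, coloured by group. Markers of monocytes and macrophages lie above the CD27SP arrays on all DP and CD11bSP arrays, with a median change over genes of 2.49 in DP cells, while B cell markers, with a median change of 0.17, overlap between the groups.

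The third comparison followed the loss of CD27 on CD11b+ cells, from DP to CD11bSP. Genes that fell outnumbered those that rose, 235 to 83. Nsg2 fell by 3.67 (SE 0.27, adjusted p = 0.000215, n = 3 and 3), Slamf6, a receptor gene of the SLAM family, fell by 3.23 (SE 0.20, adjusted p = 9.37e-05), and Bmp7, a growth factor gene, fell by 3.27 (SE 0.27, adjusted p = 0.00038). Gpr55 fell by 3.27 (SE 0.62) and Wfdc2 by 2.94 (SE 0.46), and H2-Q1 was not well above background on any CD11bSP array and was at least 5.44-fold lower there. The lymphotoxin beta gene Ltb fell by 2.92 (SE 0.26), and the glycoprotein gene Thy1 and the chemokine gene Xcl1 fell by 2.53 (SE 0.37) and 2.40 (SE 0.27). Among the genes that rose were Gpx8, a peroxidase gene (3.46, SE 0.50, adjusted p = 0.00571), Cdc42ep1 (3.40, SE 0.27, adjusted p = 0.000308), the parathyroid hormone receptor gene Pth1r (3.26, SE 0.66), Dagla (2.95, SE 0.44), Smarcd3 (2.69, SE 0.44), the potassium channel gene Kcnj8 (2.38, SE 0.35), the beta-1 adrenergic receptor gene Adrb1 (2.37, SE 0.48) and Rhpn1 (2.25, SE 0.42).

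Of 20 early NK stage markers 11 fell and 1 rose (14 and 1 adjusted over the list alone; median -0.995, adjusted p = 1.13e-14, and adjusted p = 0.14 with an estimated correlation). Il7r fell by 2.67 (SE 0.17) and Tcf7, a transcription factor gene of early lymphocytes, by 2.08 (SE 0.16). Cxcr3 fell by 2.13 (SE 0.26) and Ccr2 by 1.33 (SE 0.15), both chemokine receptor genes. Of 21 late NK stage markers 6 rose and 0 fell (13 and 1 adjusted over the list alone; median 0.80, adjusted p = 5.77e-09, and adjusted p = 0.372 with an estimated correlation). Klrg1 rose by 1.95 (SE 0.34), Cx3cr1 by 1.56 (SE 0.28), Ly6c1 by 1.43 (SE 0.23) and Gzmb by 1.19 (SE 0.25). Of 19 ILC1 markers 9 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.945, adjusted p = 5.63e-14, and adjusted p = 0.0597 with an estimated correlation). Cxcr6 fell by 1.68 (SE 0.18). Of 15 T cell markers 7 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.92, adjusted p = 3.91e-11, and adjusted p = 0.0987 with an estimated correlation). Cd3d fell by 3.05 (SE 0.32) and Cd3g by 2.75 (SE 0.23). Of 29 other NK receptors 5 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.17, adjusted p = 3e-04, and adjusted p = 0.27 with an estimated correlation). Cd160 fell by 1.94 (SE 0.18) and Crtam, an adhesion receptor gene, by 1.81 (SE 0.17). The transcription factor genes Myb, Myc and Ikzf2 fell by 1.19 (SE 0.18), 0.84 (SE 0.14) and 0.79 (SE 0.14), and Gzmm, a granzyme gene, fell by 1.60 (SE 0.23).

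Of 34 interferon response genes 7 fell and 0 rose (15 and 0 adjusted over the list alone; median -0.68, adjusted p = 7.31e-13, and adjusted p = 0.198 with an estimated correlation). The chemokine gene Cxcl10 fell by 1.84 (SE 0.25) and Ifit3 by 1.15 (SE 0.20). Of 23 cytokines and chemokines 6 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.50, adjusted p = 7.31e-06, and adjusted p = 0.27 with an estimated correlation). The 45 ribosomal protein genes had a median of -0.59, with 0 passing singly (0 rose and 2 fell adjusted over the list alone; adjusted p = 1.3e-10, and adjusted p = 0.395 with an estimated correlation). The mean of that list was 6.62, 7.6 and 7.36 on the DP arrays. It was 6.06, 7.06 and 6.71 on the CD11bSP arrays, so the 2 groups overlapped. Each CD11bSP array lay below the DP array of the same number, though the numbers did not meet the pairing rule for these groups. Of 34 genes of ribosome biogenesis and MYC 1 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.30, adjusted p = 1.38e-06, and adjusted p = 0.372 with an estimated correlation). Of 67 cell cycle genes 1 fell and 0 rose (1 and 0 adjusted over the list alone; median -0.63, adjusted p = 1.2e-10, and adjusted p = 0.395 with an estimated correlation). MHC class II genes (2 of 13 fell, 0 rose; 5 and 0 adjusted over the list alone; median -0.72, adjusted p = 7.02e-07, and adjusted p = 0.27 with an estimated correlation) shifted down. H2-Oa fell by 1.82 (SE 0.24). Markers of monocytes and macrophages (median -0.65, adjusted p = 3.72e-06) and of neutrophils (median -0.70, adjusted p = 0.000193), each at adjusted p = 0.395 with an estimated correlation, and of mast cells and basophils (median -0.59, adjusted p = 9.45e-05, and adjusted p = 0.372 with an estimated correlation) shifted down. No single member of these 3 lists passed, and adjusted over the list alone 0, 0 and 4 fell.

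The cell cycle, monocyte and macrophage and other NK receptor lists no longer passed with the slide as a block (medians -0.27, -0.55 and -0.19, adjusted p = 0.215, 0.0533 and 0.0797). The medians in that fit were -1.10 for early and 0.67 for late NK stage markers, -0.93 for ILC1 markers, -1.33 for T cell markers, -0.58 for interferon response genes, -0.81 for cytokines and chemokines and -0.96 for ribosomal proteins. They were -0.37 for ribosome biogenesis and MYC, -0.70 for MHC class II genes, -0.93 for neutrophil and -0.74 for mast cell and basophil markers. Within slide 1, CD11bSP array 1 against DP arrays 1 and 2, they were -1.18 and 0.69 for early and late NK stage markers, -0.835 for ILC1 markers, -1.23 for T cell markers, -0.59 for interferon response genes, -0.68 for cytokines and chemokines and -1.07 for ribosomal proteins. For cell cycle genes, MHC class II genes, ribosome biogenesis and MYC, and monocyte, neutrophil and basophil markers the medians there were -0.44, -0.46, -0.50, -0.43, -0.68 and -0.57. With normexp ILC1, T cell, late NK stage and mast cell and basophil markers turned direction and did not pass (adjusted p = 0.413, 0.676, 0.611 and 0.387). Nor did cell cycle genes, MHC class II genes, cytokines and chemokines, or neutrophil markers (adjusted p = 0.598, 0.424, 0.33 and 0.598).

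The 318 genes that changed between DP and CD11bSP cells became 105 with the slide as a block (8 higher, 97 lower; 97 among the 318), with all 318 in the same direction. Of the 37 genes named here that changed, 19 passed in that fit. Within slide 1 the 1 CD11bSP array against 2 DP arrays gave 57 genes (2 higher, 55 lower), with the lone array assumed to vary like the others. Without DP arrays 2 and 3 in turn the count was 168 and 167 (24 and 39 higher), and without CD11bSP array 3 it was 131 (19 higher). Without CD27SP array 3, which enters this comparison only through the shared spread once the probes are chosen, it was 205 (42 higher). The probes were not chosen anew in these fits. The genes that were higher numbered 44 without DP array 1, 52 and 47 without CD11bSP arrays 1 and 2, and 128 with CD117+ array 1 or array 2 left out.

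The last comparison set the ends of the CD27 and CD11b gates against each other, CD11bSP against CD27SP. Nsg2 fell by 7.63 (SE 0.27, adjusted p = 2.6e-07, n = 3 and 3), from 4.42 ± 0.06 to -3.21 ± 0.20 (SD), Cd3d fell by 6.99 (SE 0.32, adjusted p = 6.5e-07), Bmp7 fell by 6.97 (SE 0.27, adjusted p = 2.87e-07) and Il7r fell by 6.42 (SE 0.17, adjusted p = 1.07e-07). Dapl1 fell by 6.65 (SE 0.47) and Lypd6b fell by 6.52 (SE 0.27). Lratd1 and Adh1 were not well above background on any CD11bSP array and were at least 49.9 and at least 24.8-fold lower there. Gpx8 rose by 5.43 (SE 0.50, adjusted p = 5.69e-05), Adrb1 by 4.67 (SE 0.48), Klrg1 by 4.56 (SE 0.34, adjusted p = 1.64e-05), the TNF family gene Tnfsf12 by 4.42 (SE 0.56; 1.85, adjusted p = 0.157, with the slide as a block), Cma1 by 4.27 (SE 0.56) and the metalloprotease gene Mep1a by 4.15 (SE 0.38; 2.60, adjusted p = 0.0471, with the slide as a block). Gngt1 and Dagla were not well above background on any CD27SP array and were at least 17.4 and at least 10.8-fold higher in CD11bSP cells.

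Of 19 ILC1 markers 17 fell and 0 rose (17 and 1 adjusted over the list alone; median -2.49, adjusted p = 4.82e-16). Of all list calls in the 4 comparisons only this one also passed without the preset correlation (adjusted p = 0.038 with an estimated correlation). With normexp the median of the ILC1 list was only -0.177 (adjusted p = 0.0218 in camera). Of its 19 markers 15 stand in another list too, so its fall is not wholly separate from those of other lists. Cd3g and Cxcr6, both in the ILC1 list, fell by 6.06 (SE 0.23) and 5.25 (SE 0.18), and Pdcd1, the gene of the inhibitory receptor PD-1, fell by 4.42 (SE 0.31). Of 20 early NK stage markers 14 fell and 1 rose (14 and 2 adjusted over the list alone; median -2.87, adjusted p = 8.99e-12, and adjusted p = 0.153 with an estimated correlation). Ltb fell by 4.56 (SE 0.26), Gpr183 by 3.44 (SE 0.21), Tcf7 by 3.15 (SE 0.16) and Tnfsf10 by 2.84 (SE 0.21). Of 21 late NK stage markers 14 rose and 0 fell (15 and 0 adjusted over the list alone; median 1.76, adjusted p = 1.08e-08, adjusted p = 0.29 with normexp, and adjusted p = 0.321 with an estimated correlation). Cx3cr1 rose by 3.95 (SE 0.28), Gzmb by 3.03 (SE 0.25) and Prf1, the perforin gene, by 2.27 (SE 0.27). The transcription regulator genes Id3, Ikzf2 and Bcl11b fell by 4.29 (SE 0.27), 3.79 (SE 0.14) and 3.69 (SE 0.29). Lta and Tnf, cytokine genes, fell by 5.58 (SE 0.24) and 4.03 (SE 0.21), the receptor genes Slamf6 and Cd160 by 4.64 (SE 0.20) and 3.46 (SE 0.18), and Gzmm by 2.79 (SE 0.23). Of 15 T cell markers 14 fell and 0 rose (14 and 0 adjusted over the list alone; median -3.67, adjusted p = 4.09e-15, and adjusted p = 0.063 with an estimated correlation). T cells in the CD27SP sort stay open as a source of the T cell marker falls. Of 11 Ly49 receptor genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; median 1.52, adjusted p = 7.47e-06, adjusted p = 0.764 with normexp, and adjusted p = 0.143 with an estimated correlation). Klra6 rose by 2.18 (SE 0.24; 1.18, adjusted p = 0.0636, with the slide as a block) and Klra10 by 1.75 (SE 0.18).

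Of 34 genes of ribosome biogenesis and MYC 17 fell and 0 rose (23 and 0 adjusted over the list alone; median -0.68, adjusted p = 2.69e-09, and adjusted p = 0.228 with an estimated correlation). Of 45 ribosomal protein genes 15 fell and 0 rose (16 and 0 adjusted over the list alone; median -0.76, adjusted p = 1.54e-08, and adjusted p = 0.638 with an estimated correlation). The mean of that list overlapped between the groups, at 7.02 on CD27SP array 1 and 7.06 on CD11bSP array 2. For each replicate number it was lower in CD11bSP cells. It was 7.02, 7.55 and 7.51 on CD27SP arrays 1, 2 and 3, and 6.06, 7.06 and 6.71 on CD11bSP arrays 1, 2 and 3. Of 34 interferon response genes 12 fell and 1 rose (15 and 2 adjusted over the list alone; median -0.39, adjusted p = 7.47e-06, and adjusted p = 0.321 with an estimated correlation). Cxcl10 fell by 2.13 (SE 0.25), Ifit1 by 2.02 (SE 0.20) and Ifit3 by 1.89 (SE 0.20). Monocyte and macrophage markers stayed above the CD27SP level (26 of 29 rose, 0 fell; 28 and 0 adjusted over the list alone; median 1.81, adjusted p = 1.24e-14, and adjusted p = 0.237 with an estimated correlation). F13a1 rose by 2.79 (SE 0.47) and the scavenger receptor gene Cd163 by 2.55 (SE 0.19). Of 67 cell cycle genes 4 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.38, adjusted p = 0.0228, and adjusted p = 0.929 with an estimated correlation), a call lost with quantile scaling (adjusted p = 0.0642), with array weights (adjusted p = 0.0704) and without CD27SP array 2 or 3 or CD11bSP array 1 or 2 (adjusted p = 0.107, 0.304, 0.273 and 0.0845). Of 18 NK identity genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; median 0.47, adjusted p = 0.106; adjusted p = 0.0442 with the replicate number as a block and 0.000266 with quantile scaling; with normexp they passed downwards, median -0.80, adjusted p = 0.00374). The falls were those of Cd7 (by 2.00, SE 0.37) and the interleukin-2 receptor gene Il2rb (by 0.93, SE 0.25). Slide-block medians were -2.51 for ILC1 markers, -2.72 for early and 1.52 for late NK stage markers, -2.73 for T cell markers, 1.44 for Ly49 receptors, -0.51 for ribosome biogenesis and MYC and -0.91 for ribosomal proteins. They were -0.535 for interferon response genes, 1.67 for monocyte and macrophage markers, 0.565 for cell cycle genes and 0.27 for NK identity genes.

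Between CD27SP and CD11bSP cells 1629 genes rose and 1394 fell, 3023 in all. Scaling to the array median gave 1083 higher and 1474 lower, with the median of all genes shifted to -0.22. Adding the slide as a block, 364 genes remained or appeared (99 higher, 265 lower; 354 among the 3023), 97.8% of the 3023 kept their direction and the median SE went from 0.222 to 0.359. Of the 43 genes named here that changed, 28 passed in that fit. No slide held both groups, so no value within a slide could be had. Without CD27SP array 3 the count was 1979 (1096 higher, 883 lower). The remaining pairs were counted only: 1623 genes differed between DP and CD117+ cells (946 higher in DP cells, 677 lower) and 2341 between CD11bSP and CD117+ cells (1113 higher in CD11bSP cells, 1228 lower). These splits depended on which CD117+ array was left out: without array 1 they were 704 higher and 1652 lower, and 728 higher and 1948 lower, and without array 2 they were 1081 higher and 412 lower, and 1204 higher and 790 lower. With the slide as a block these counts were 1407 and 2917, and with the array median as the scale 1106 higher and 438 lower, and 1427 higher and 686 lower.

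**Figure D3:**
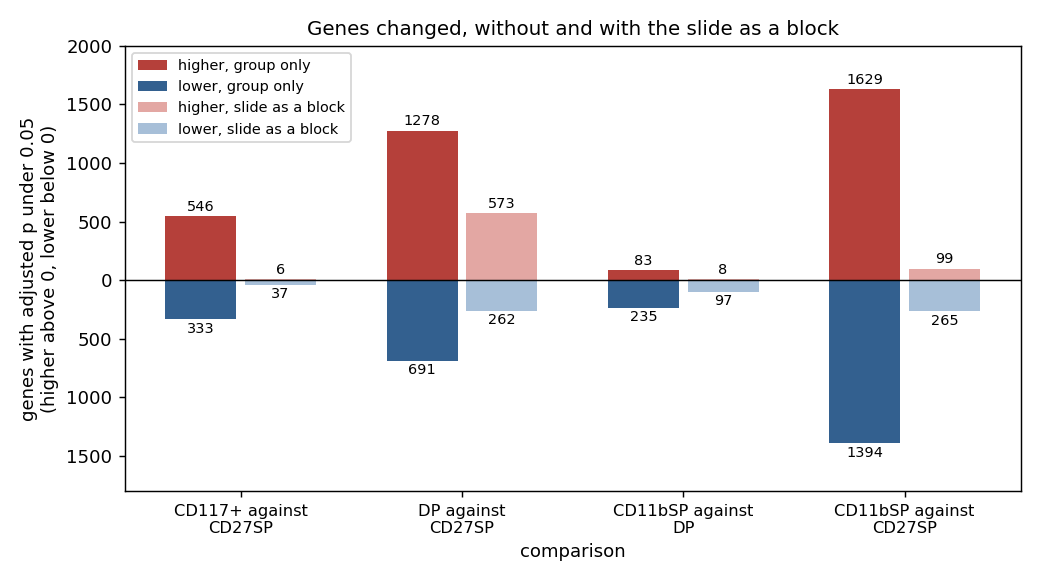
Bars give the number of genes with a limma adjusted p under 0.05 on the y axis, higher above 0 and lower below 0, for the 4 comparisons on the x axis; dark bars are the fit with group means alone and light bars the fit with the slide as a block. The count goes from 879 to 43 for CD117+ against CD27SP cells and from 3023 to 364 for CD11bSP against CD27SP cells, 2 pairs that share no slide.

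Where the intermediate groups lay was measured over 3021 of the genes that changed between CD27SP and CD11bSP cells, with CD27SP at 0 and CD11bSP at 1. The median position of DP cells was 0.689 (SD 0.116 over 3 arrays), and 71.2% of these genes had a DP mean between both ends and 26.5% one beyond the CD11bSP end (43.3% of the genes that rose). Genes that rose towards CD11bSP cells had already come to 0.848 in DP cells, and genes that fell to 0.615. CD117+ cells had a median position of 0.237 (0.161 and 0.292 on the single arrays), with 61.2% of the genes between both ends and 30.3% beyond the CD27SP end. In 20 simulated draws in which the group equalled CD27SP, the mean position was 0.045 for DP and 0.044 for CD117+ cells, which the shared CD27SP arrays produce. The draws held independent noise and no slide effect. No CD117+ or CD11bSP array shared a slide with the CD27SP arrays, so any shift that a slide effect adds is left out. With the slide as a block the positions were 0.624 for DP cells and 0.094 for CD117+ cells, and with normexp 0.335 and 0.808, in the other order. Each of these fits took the genes that it called itself, 364 with the slide as a block and 9577 with normexp, sort genes left out. These positions therefore differ from the first in the genes as well as in the method.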

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

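The tests for the T cell markers and for the myeloid, platelet and erythroid markers below were chosen after the results were seen. Probes without a gene name were not used in the report's comparisons and held signal: of 8278 such probes tested with limma, 168 passed between CD117+ and CD27SP cells (104 higher, 64 lower), 260 between DP and CD27SP cells (163 higher, 97 lower), 31 between CD11bSP and DP cells (2 higher, 29 lower) and 565 between CD11bSP and CD27SP cells (318 higher, 247 lower). Which genes they read is not known here, so a gene of the sort molecules is not excluded for probe A_51_P355906, which was 3.38 higher in CD117+ than in CD27SP cells (SE 0.444, adjusted p = 0.00473). Besides it, probe A_52_P557517 was lower in CD117+ cells (-5.66, SE 0.556, adjusted p = 0.000922), and probe A_52_P200125 was lower in CD11bSP than in CD27SP cells (-7.43, SE 0.322, adjusted p = 8.06e-07).

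In CD117+ cells, genes at the background in the other groups read well above background. Of 2836 such genes 65 did so on CD117+ array 1, 1641 on array 2 and 47 on both, 1.25 times the 37.61 that independent arrays give. With 65 genes the ratio was bound to stay at or under 1.73, and array 2 gave 0.993 to 1.5 with the 9 arrays of other groups, so independent noise stays open. Genes picked as the dimmest 25% by their CD27SP mean tend to read higher on other arrays. They lay 0.249 to 0.697 above the CD27SP level on the DP and CD11bSP arrays. On CD117+ array 2 they lay 1.38 above it, and on CD117+ array 1 0.283. Without array 2, 38 of the 67 genes that were higher in CD117+ cells and at the background in CD27SP cells still passed (0.567), between the bounds set beforehand, so a raised dim signal on array 2 cannot be told apart from expression in CD117+ cells with 2 arrays.

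T cell marker genes were higher in CD27SP than in CD117+ cells. The slide that held all CD27SP arrays stays open: DP array 3, the 1 other array on it, read the 7 markers that passed above DP arrays 1 and 2 by 0.483, against 2.48 between CD27SP and CD117+ cells (0.19 of it), while the slide as a block took the median of the list from -1.01 to -0.495 (adjusted p = 1.15e-06) and that of the 7 markers from -2.48 to -2.96, with Cd5 and Cd6 still passing and 5 not, in a fit that reads the slide from DP array 3. T cells in the CD27SP sort stay open too. Cd8a was higher there by 2.48 on the probe used (1.45 with the slide as a block, adjusted p = 0.294). Another Cd8a probe, above background on all arrays, read 0.275 higher in CD117+ cells, and with normexp Cd8a was 0.92 higher there. Cd8a therefore does not settle the question. Cd4 was not higher in CD27SP cells (-0.969), and the sort stained for CD3ε. Of the 15 measured markers 6 stand in another list too, and all 15 were above background on every CD27SP array. Expression of these genes by CD27SP cells themselves was not tested. The falls of T cell markers from CD27SP to DP and CD11bSP cells start from the same CD27SP arrays. T cells in that sort stay open for these falls too.

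Markers of myeloid cells, basophils, platelets and erythroid cells were higher in DP and CD11bSP than in CD27SP cells. A lower share of NK cells in the CD11b+ sorts that raised all other types alike stays open. The lists set against it were picked after their shifts had been seen. The ILC2 and dendritic cell lists held both rises and falls, so their medians need not follow a share of cells. Neutrophil, mast cell and basophil, progenitor, erythroid and platelet lists rose about as much as the monocyte list (medians 2.67, 2.54, 2.39, 2.19 and 2.13). Monocyte markers rose by a median of 2.49 (SD 0.515 over genes). ILC2, dendritic cell and plasma cell markers, of types not stained for, had 0.197, 0.397 and 0.602 (SD 1.43, 1.94 and 0.876), at most 0.24 of it. Of the 15 ILC2 and 15 dendritic cell markers 9 and 4 stand in another list too. A lower share with more of only some other types, such as CD11b+ cells, is not weighed by these lists. The slide stays open: within slide 3 the monocyte median was 0.884 of that over all arrays, but from 1 DP array, and the CD117+ arrays, on other slides, had a median of 0.00242 against CD27SP cells (-0.314 with the slide as a block, adjusted p = 0.00971), but of 0.736 with normexp (adjusted p = 0.0198), where the DP median was 1.58. CD11b+ cells of other types, past the NK1.1 gate and without CD27, would keep monocyte markers up in CD11bSP cells, which had -0.65 against DP cells, -0.547 with the slide as a block (adjusted p = 0.0533) and -0.431 within slide 1, a fall that fewer such cells in that sort would give too, so this stays open. It stays open for erythroid genes, which rose 0.88 times as much as monocyte genes but without Hba-a1 and Alas2 (0.302 and -0.182, adjusted p = 0.82 and 0.92), as does a change in the cells' own expression, which was not tested.

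The 6 arrays of each pair of groups of 3 can be split in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 1969, 318 and 3023 genes for DP against CD27SP, CD11bSP against DP and CD11bSP against CD27SP cells, and the highest other split gave 0 with limma in each. Each other split held arrays of both cell groups on either side, so the real difference entered the spread and low counts follow by construction. The 0 is therefore no measure of what arrays without a group difference would give. The splits moved arrays across slides and replicate numbers, in a fit without a block for either.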

How the results depend on the processing

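The alternatives with the scan day as a block were chosen after the results were seen. Of the 52, 53, 39 and 45 genes named in the 4 comparisons (in the report's order), 1178, 1283, 877 and 1132 values over the alternatives kept direction and call, 149, 77, 127 and 30 were weaker, 5, 0, 0 and 0 were stronger and 6, 2, 6 and 2 turned direction. Signal over background limits the dim genes. Changes are bounds only for genes dim on all arrays of the dimmer group. Leaving out each array in turn gave 392 to 2295 genes for CD117+ against CD27SP cells, 1261 to 2641 for DP against CD27SP, 131 to 408 for CD11bSP against DP, 1979 to 3516 for CD11bSP against CD27SP, 1298 to 2356 for DP against CD117+ and 1863 to 2676 for CD11bSP against CD117+. A lone CD117+ array is then assumed to vary like the other groups. The lists that passed numbered 7 to 15, 14 to 17, 18 to 23 and 15 to 17. The positions, over the genes that each fit called, ran from 0.631 to 0.815 for DP and from 0.146 to 0.372 for CD117+ cells.

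With the replicate number as a block the counts were 2911 for DP against CD27SP and 4463 for CD11bSP against CD27SP cells, the pairs of groups whose numbers were found to pair the arrays, and 1559 for CD117+ against CD27SP and 739 for CD11bSP against DP cells, where the numbers were not found to pair the arrays, and with CD117+ array 2 put with number 3 they were 2157 and 868, and 3656 for CD11bSP against CD117+ cells. Within DP and CD11bSP cells the array numbered 3 correlated with its own number at 0.0089 only. The block changed these list calls besides those in the report: for CD117+ against CD27SP cells monocyte and neutrophil markers passed (adjusted p = 0.00415 and 0.0192) and plasma cell markers did not (adjusted p = 0.101), and for CD11bSP against DP cells oxidative phosphorylation passed (adjusted p = 0.0179). It changed no other list call. With CD117+ array 2 put with number 3, early NK stage, ribosomal protein and plasma cell lists did not pass for CD117+ against CD27SP cells (adjusted p = 0.0522, 0.198 and 0.148), nor ILC3 markers for DP against CD27SP (adjusted p = 0.154) and B cell markers for CD11bSP against DP (adjusted p = 0.0646). There NK identity genes and ribosomal proteins passed for DP against CD27SP (adjusted p = 0.0205 and 0.0136), oxidative phosphorylation for CD11bSP against DP and against CD27SP (adjusted p = 0.00625 and 0.0448) and NK identity genes for the last (adjusted p = 0.0327).

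The cause was not tested for any value in this paragraph unless stated. The slide as a fixed block gave 43, 835, 105 and 364 genes for the 4 comparisons in the report's order, with wider errors by construction where the groups share no slide, and the slide as a random block 434 for the first and 1745 for the last. Besides the lists in the report the slide as a fixed block made oxidative phosphorylation pass for CD11bSP against DP and ILC2 markers for CD11bSP against CD27SP cells, both downwards (adjusted p = 0.0205 and 0.02). With the scan day as a block the counts were 27, 708, 167 and 412. At an adjusted p under 0.01 they were 330, 1172, 139 and 1747, and 981 for DP and 1377 for CD11bSP against CD117+ cells, by the stricter threshold, and with a 2-fold threshold added the last comparison had 1841. Without the filter on dim probes CD117+ against CD27SP had 551 and CD11bSP against DP 185. With the array median as the scale CD11bSP against DP had 202. Array weights gave 3262, 644 and 6749 for DP against CD27SP, CD11bSP against DP and CD11bSP against CD27SP. Fits of the 2 groups alone gave 511 for the first, 955 for DP against CD117+ and 1194 for CD11bSP against CD117+ cells. With an estimated correlation 0, 0, 0 and 1 lists passed.

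With normexp the counts were 13, 162, 0 (3072 at an unadjusted p under 0.05 in limma) and 9577, with the median of all genes at 0.118 in the last, and 28 for DP and 9 for CD11bSP against CD117+ cells; 19 lists passed for CD117+ against CD27SP and 12 for CD11bSP against DP. The cause was not tested. In the first comparison the monocyte, platelet, mast cell and erythroid lists then passed upwards (adjusted p = 0.0198, 0.0263, 0.000648 and 0.00249) and NK identity genes downwards (adjusted p = 0.0116), as they did for CD11bSP against DP (adjusted p = 4.31e-05). In that alternative these genes turned direction: Tdrp (0.381), Lratd1 (0.0222), Cd8a (0.92) and Ncr1 (-0.0088) in the first comparison, Susd4 (0.17) and Atp6v0d2 (0.0438) in the second, H2-Q1 (1.46), Gpr55 (1.47), Bmp7 (0.296), Wfdc2 (0.462), Ikzf2 (0.476) and Itgam (-0.419) for CD11bSP against DP and Lratd1 (0.45) and Adh1 (1.01) in the last. Cd8a turned also with probes kept only if above background on all arrays (0.275), where another of its probes was used. Itgam, which did not pass in the first comparison, ran from -0.874 to 0.125 as arrays were left out. The DP position was 0.335 with normexp, and that of CD117+ cells 0.808 with normexp, 0.351 with the array median as the scale, 0.094 with the slide as a fixed block and 0.116 with it as a random block. Each was taken over the genes that its own fit called, and the cause was not tested.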

Other observations

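All values here come from lists and arrays fixed before the files were read, and the haemoglobin and haem genes at the end were chosen after their values were seen. From DP to CD11bSP cells more lists shifted down. Of 16 ILC3 markers 3 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.57, adjusted p = 7.02e-07, and adjusted p = 0.0987 with an estimated correlation; -0.62 with the slide as a block), and of 15 ILC2 markers 2 fell and 0 rose (2 and 0 adjusted over the list alone; median -0.48, adjusted p = 0.00198, and adjusted p = 0.395 with an estimated correlation; -0.715 with the slide as a block). Progenitor markers had a median of -0.44 with no member passing (adjusted p = 0.000933, and adjusted p = 0.4 with an estimated correlation; -0.81 with the slide as a block). Dendritic cell, erythroid, platelet and B cell markers had medians of -0.45, -0.456, -0.52 and -0.18 (adjusted p = 0.0182, 0.00332, 0.0166 and 0.0473, and adjusted p = 0.372, 0.392, 0.4 and 0.532 with an estimated correlation). These 4 lists no longer passed with the slide as a block (adjusted p = 0.11, 0.516, 0.215 and 0.365), and with normexp B cell markers shifted up (adjusted p = 0.0211). The erythroid, platelet and B cell lists did not pass without DP array 1 (adjusted p = 0.0549, 0.103 and 0.381) or CD11bSP array 3 (adjusted p = 0.0612, 0.1 and 0.286), nor B cell markers without CD27SP array 2, DP array 2 or CD11bSP array 2 (adjusted p = 0.0516, 0.0619 and 0.226). With normexp the ILC3, ILC2, progenitor, dendritic cell and erythroid lists turned direction and did not pass (adjusted p = 0.191, 0.517, 0.0969, 0.191 and 0.867), and platelet markers did not pass (adjusted p = 0.598).

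Between CD27SP and CD11bSP cells the markers of other blood cells stayed up. Mast cell and basophil markers rose in 14 of 16 genes (14 adjusted over the list alone; median 1.92, adjusted p = 5.37e-09, and adjusted p = 0.153 with an estimated correlation), neutrophil markers in 16 of 21 (17 adjusted over the list alone; median 1.93, adjusted p = 1.9e-08, and adjusted p = 0.284 with an estimated correlation) and platelet markers in 14 of 16 (15 adjusted over the list alone; median 1.53, adjusted p = 1.37e-09, and adjusted p = 0.153 with an estimated correlation). Erythroid markers rose in 10 of 16 (11 adjusted over the list alone; median 1.60, adjusted p = 9.03e-06, and adjusted p = 0.208 with an estimated correlation) and progenitor markers in 16 of 23 (19 adjusted over the list alone; median 1.83, adjusted p = 1.35e-07, and adjusted p = 0.284 with an estimated correlation). No gene of these lists fell. Their medians with the slide as a block were 1.76, 1.33, 1.38, 1.69 and 1.41. Of 16 ILC3 markers 9 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.83, adjusted p = 0.000379, and adjusted p = 0.153 with an estimated correlation; -0.675 with the slide as a block, and adjusted p = 0.7 with normexp, which turned its direction).

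The arrays numbered 2 read Hba-a1, a haemoglobin gene, and Alas2, a haem synthesis gene, low in 3 groups: 1.05 and -4.38 on CD27SP array 2, 1.90 and -3.96 on DP array 2 and 1.54 and -3.81 on CD11bSP array 2. CD117+ array 2 read 2.81 and -1.95, and the other arrays 2.97 to 3.53 and -2.22 to -1.51.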
